A study of Mus musculus and Homo sapiens with 10 samples.

How the data were processed

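The series holds 10 samples. RNA from 2 of them, wild-type MEF at passage 3 and at passage 11, was hybridised to single-colour Agilent arrays, and these 2 arrays were analysed. The deposited values are spot intensity values written by Agilent Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12, per the file headers, which also name the genome build mm9. The column used is the software's processed signal, and each spot carries an error for that signal, called the error-model error in the text. The background and other steps behind the processed signal are not given in the sources used here, and a step that differed between the arrays would enter the differences. The other 8 samples were run on Illumina arrays, processed with GenomeStudio per the submitters' processing notes. Their 4 tables name columns by chip position only, which no label ties to a sample, so their 64 per-sample columns were not used. The 9 comparisons and the agreement between passage 7 and passage 11 that need them were not analysed here.

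The 43020 non-control spots of each array entered, and 327 spots that carried an outlier flag on either array were left out. The log2 processed signal of each array was shifted so that its 75th percentile matched on both arrays, and spots of 1 probe were averaged. A probe counted as detected where the scanner marked it well above background. Of 39412 probes, 27498 were named by matching the unversioned accession in the files to the GRCm38.p6 gene table, giving 20880 genes. The other 11914 probes were left unnamed and out of the gene results. As the table's assembly differs from the build of the files, it was used for names only and no coordinates are given. For a gene with several probes the probe with the highest mean signal was used. Of 3174 genes with 2 or more probes measured on both arrays, 8 had probes 2-fold or more in opposite directions, and the median range between probes was 0.31 log2. Where 1 array was not well above background, it entered at the higher of its own value and the lowest signal well above background on that array, and the fold is given as "at least". No fold is given where the bound fell under 1 or neither array was above background.

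Each group is 1 array, so no test was run. Genes were counted at 2-fold or more among those detected on at least 1 array. Before the data were examined, 38 gene lists were fixed, together with the comparison, the settings and the rule for named genes. A list is described by its counts, the median log2 difference of its detected members, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 5 measured members have no percentile. Of 36 lists with a percentile, 14 lay below percentile 2.5 and 7 above 97.5. The rule for names took Foxp3, Trp53, Cdkn1a, Mdm2 and Cdkn2a always, the 6 highest and 6 lowest genes past 2-fold with an established symbol, and up to 4 members of each list with the widest differences past 2-fold. Bounds enter that ranking but have no order among themselves. Some genes that the rule names are not reported here, and they still count in their lists.

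The procedure was tested on simulated data for this comparison. In 12999 genes with noise from the scanner's error model, 40 genes at each fold were altered. Those past 2-fold were 7.5% at 1.5-fold, 52.5% at 2-fold, 100% at 3-fold, 95% at 4-fold and 100% at 8-fold. The 2 missed at 4-fold lay near the floor, where only a bound can be given. The pass mark of this check was first set above 95% and lowered to 90% after that result was seen. Of 12799 unaltered genes, 0.96% passed 2-fold. Of 200 lists of unaltered genes, 3.5% lay outside the middle 95% of random lists. This noise leaves out differences between cultures. It was drawn separately for each gene, so lists whose genes vary together were not checked. Both simulated arrays were given the passage 3 floor, whereas the floors of the real arrays differ.

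Alternatives fixed in advance were scaling to the median of all probes, quantile normalization, no filter and no bounds, detection on both arrays, thresholds of 1.5-fold and 3-fold, and the mean over detected probes. The planned background correction on mean spot signals was not run, because the files analysed hold no such column. In its place, and chosen after seeing the data, limma 3.58.1 in R 4.3.3 ran normexp with an offset of 50 on median signals, then quantile normalization. Scaling to probes above background on both arrays was also added after seeing the data. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.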

Results

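Gene expression was measured in mouse embryonic fibroblasts (MEF), primary cells grown from mouse embryos that stop dividing after a limited number of passages. The labels call the passage 11 cells senescent, a term for cells permanently out of the cell cycle, but arrest itself was not measured. Wild-type MEF at passage 3 and at passage 11 were each hybridised to 1 single-colour Agilent array. Each group is therefore 1 array. The differences have no replicate check, no p-value is given, and "higher" and "lower" describe these 2 arrays. The arrays lay on 2 slides scanned on 2 days, so slide, scan day and passage cannot be told apart. Of 39412 probes, 21538 (54.6%) were well above background at passage 3 and 24444 (62.0%) at passage 11. No spot was saturated. The lowest signal among probes well above background was 41.3 at passage 3 and 22.6 at passage 11, so dim genes were measured less deeply at passage 3. The number of arrays limits the precision. The scanner's error model gave a median standard error of 0.20 for a log2 difference between the arrays, and replicate spots of 1 probe had a standard deviation of 0.09 log2 at passage 3 and 0.08 at passage 11. Both errors cover measurement within an array only. The series compared 10 groups in all, and the 9 comparisons that need the Illumina arrays were not analysed here, because the columns of those tables could not be given to samples.

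The comparison of passage 11 with passage 3 asks which genes differ between young and senescent fibroblasts, in a study concerned with p53 and the transcription factor Foxp3. Foxp3, best known as the regulator of regulatory T cells, had 1 probe. Its scaled signal was 31.2 at passage 3, not well above background, and 30.4 at passage 11, well above background but under the passage 3 floor, so no fold is given. Trp53, which encodes p53, was 2.11-fold lower at passage 11 (log2 difference -1.08 ± 0.21, error-model SE, as for every ± that follows). Cdkn1a, the p21 cell cycle inhibitor that p53 induces, was 2.96-fold lower (-1.56 ± 0.20), from 21289.8 to 7199. Mdm2, the ubiquitin ligase that degrades p53 and is itself a p53 target, was 3.71-fold lower (-1.89 ± 0.20). Cdkn2a, the locus of the p16 and p19Arf cell cycle inhibitors, was 3.68-fold higher (1.88 ± 0.20), from 23634 to 86959.

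Across the transcriptome, 14687 of 20880 named genes were well above background on at least 1 array, and 14161 of them had a fold. Of these, 2389 were 2-fold or more higher and 2439 were 2-fold or more lower at passage 11, and 6416 (45.3%) differed by less than 1.5-fold. Of the 4828 genes past 2-fold, 1024 rested on a bound because 1 array was not well above background, 552 of them higher and 472 lower. Of the other 3804, 3791 differed by more than 3 error-model SE. At a median SE of 0.20 the 2-fold threshold nearly ensures this, so it adds no separate support. Scaling to the median of all probes moved the median of all genes by -0.25 log2 and gave 1777 higher and 3214 lower, so the higher share of these genes went from 49.5% to 35.6%. Cytl1, Cnmd (chondromodulin), Col26a1 and Gdf10 were not well above background at passage 3 and were at least 468-fold, 376-fold, 263-fold and 251-fold higher. Sfrp2, a secreted Wnt modulator, was 194-fold higher (7.60 ± 0.21), and Omd (osteomodulin), a bone matrix proteoglycan, was 178-fold higher (7.48 ± 0.23). Crct1, Gjb2 (a gap junction connexin), Pkp1 (plakophilin, a desmosome protein) and Lce1g were at least 588-fold, 519-fold, 262-fold and 195-fold lower and not well above background at passage 11. Lce1i, a late cornified envelope gene, was 159-fold lower (-7.31 ± 0.25), and Plac8 was 147-fold lower (-7.20 ± 0.26).

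**Figure D1:**
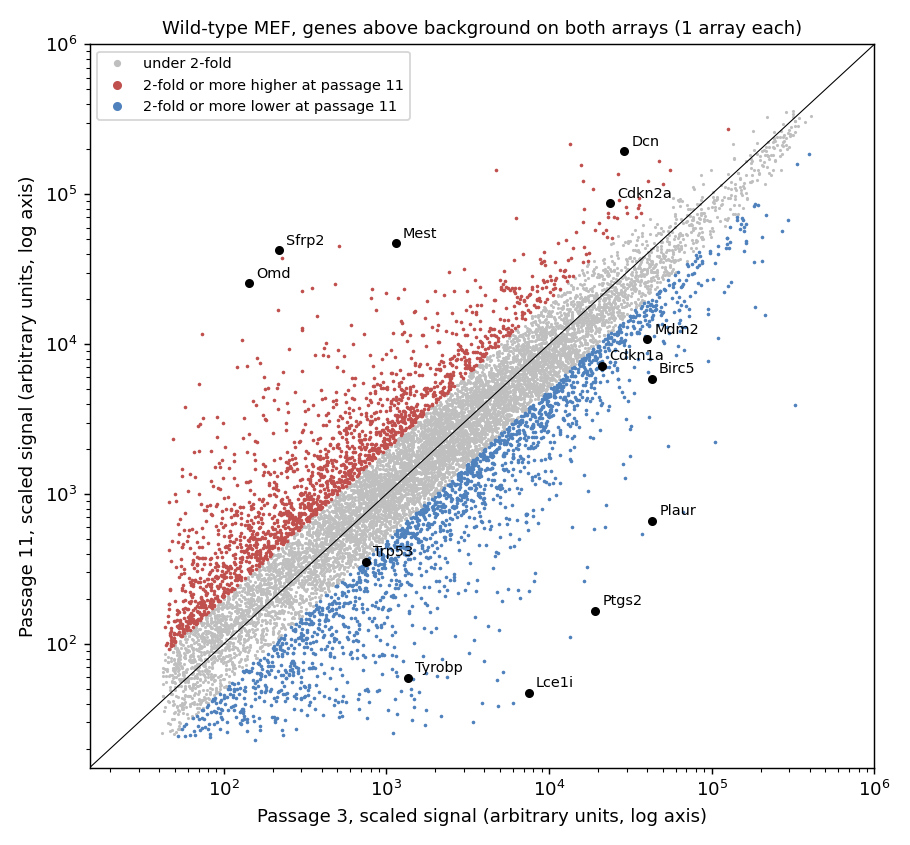
Scaled signal of each named gene at passage 3 (x axis) and passage 11 (y axis), in arbitrary units on log axes, for the 12516 genes well above background on both arrays. Red and blue points lie 2-fold or more from the diagonal line of equal signal, and black points mark named genes, among them Cdkn2a above the line and Trp53, Cdkn1a and Mdm2 below it.

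Most genes of mitosis and DNA replication were lower, while related lists were lower in part. In the mitosis list, 47 of 49 measured members were 2-fold or more lower and 0 were 2-fold or more higher. Its median log2 difference was -1.97, below each of 10000 random lists of like size and expression, whose middle 95% ran from -0.32 to 0.32. Aurka, a spindle kinase, was 8.22-fold lower, Birc5 (survivin) 7.26-fold, Cenpe, a kinetochore motor, 6.90-fold and Prc1, a midzone protein, 5.90-fold. All of them were still well above background at passage 11, at scaled signals of 1662.9, 5878.6, 2069.7 and 3129.3. A full arrest of the culture is therefore not shown. In the DNA replication list, 31 of 41 members were lower and 0 higher (median -1.37, below each random list). Rrm2, the small subunit of ribonucleotide reductase, was 11.48-fold lower, Uhrf1 5.42-fold and Gmnn (geminin) 5.51-fold, and Orc1 was at least 9.18-fold lower. Of 24 E2F and DREAM regulators, 8 were lower and 0 higher (median -0.80, percentile 0.07), and 13 were lower when scaled to the median of all probes. E2f7 and E2f8 were 9.42-fold and 9.35-fold lower, Ccne1 (cyclin E) 7.72-fold and Mybl2 6.58-fold. Of 33 DNA damage response and repair genes, 13 were lower and 0 higher (median -0.79, below each random list), with Clspn (claspin), Fanca, Exo1 and Rad51ap1 between 6.47-fold and 3.98-fold lower. Replication-dependent histones went both ways, with 12 of 26 lower and 5 higher (median -0.82, percentile 0.1). The excess of lower histones depended on the processing. Quantile normalization gave 5 lower and 5 higher (median -0.65). Normexp on median signals, then quantile normalization, gave 4 lower and 3 higher (median -0.45). H2ac4 was 4.56-fold lower, while H2ac6, H2bc6 and H1f3 were 3.60-fold, 3.15-fold and 3.03-fold higher. These histone genes have near-identical copies, and their probes may not separate them.

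The ribosome biogenesis, sterol synthesis, contractile and heat shock lists had medians below the middle 95% of random lists. Of 31 ribosome biogenesis genes, 24 were lower and 0 higher (median -1.26, below each random list), with Ddx21, a nucleolar helicase, 7.90-fold lower and Rrp12, Rrp9 and Rrs1 4.89-fold, 4.83-fold and 3.71-fold lower. Of 27 cholesterol and lipid synthesis genes, 15 were lower and 0 higher (median -1.02, below each random list), against 9 lower under quantile normalization and 8 under normexp. Idi1, Msmo1 and Lss were 5.79-fold, 5.21-fold and 3.31-fold lower. Of 17 smooth muscle and myofibroblast genes, 11 were lower and 2 higher (median -1.46, below each random list). Acta2, smooth muscle actin, was 4.74-fold lower, Actg2 6.27-fold and Lmod1 9.75-fold lower, and Tgfb2 was 4.64-fold higher. Of 19 heat shock genes, 9 were lower and 1 higher (median -0.77, percentile 0.66), against 5 lower under quantile normalization (median -0.38) and under normexp (median -0.37). Hspb1, Hspa4l and Hspa4 were 5.55-fold, 4.11-fold and 3.66-fold lower, and Hspa1a was 3.04-fold higher.

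Direct targets of p53 were more often lower than higher, at 18 lower and 6 higher of 50 (median -0.68, below each random list). The median was -0.42 under quantile normalization and -0.41 under normexp, and scaling to the median of all probes gave 25 lower and 3 higher. The 4 members with the widest differences were lower. Perp, a desmosome-associated gene that stratified epithelia also express, was 62.3-fold lower, Gtse1, a gene of dividing cells, 12.4-fold, Pmaip1 (Noxa, a proapoptotic BH3-only protein) 11.49-fold and Epha2 7.47-fold. The higher members included Ddb2, Gadd45a and Sesn1, at 7.45-fold, 5.68-fold and 5.55-fold higher, which were chosen after their values were seen. Of 29 cell cycle inhibitors and senescence regulators, 11 were lower and 7 higher (median -0.26, percentile 18.8, -0.51 to -0.26 over the other settings), so the list as a whole lay within the random lists. Lmnb1 (lamin B1, whose loss is used as a senescence marker) was 4.55-fold lower, Igfbp5 was 21.9-fold higher and Cdkn1c (p57) was 12.4-fold higher.

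Genes of the senescence-associated secretory phenotype (SASP), the cytokines, proteases and protease inhibitors that senescent cells are known to release, were more often lower than higher, at 22 lower and 9 higher of 43 (median -1.25, below each random list, and -0.83 under normexp). Plaur (the urokinase receptor) was 64.9-fold lower, and Serpinb2 and Ccl8 were at least 107-fold and 51.5-fold lower. Of 26 NF-kB regulators and targets, 8 were lower and 3 higher (median -0.23, percentile 14.5, and -0.48 at percentile 15.8 when scaled to the median of all probes). Its cytokines Ccl5, Il6 and Ccl2 were 7.84-fold, 6.37-fold and 5.80-fold lower and Ier3 was 6.04-fold lower. Macrophage markers were lower too, at 14 lower and 0 higher of 18 (median -2.53, below each random list; 9 of 13 among those detected on both arrays), with Ctss, C1qc and Tyrobp 39.1-fold, 23.7-fold and 22.8-fold lower and C1qa at least 18.8-fold lower. Interferon-stimulated genes ran the other way, with 10 higher and 2 lower of 31 (median 0.63, percentile 99.8, and 0.38 when scaled to the median of all probes). Stat2, Ifit1 and Ifit3 were 5.15-fold, 5.06-fold and 4.98-fold higher, and Oas1g was at least 7.37-fold lower. Immediate early genes went both ways, with 8 lower and 6 higher of 22 (median -0.33, percentile 12.6, -0.57 to -0.15 over the other settings). Fosl1, an AP-1 subunit, was 79.7-fold lower, while Fos and Ier2 were 5.74-fold and 4.40-fold higher.

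Of 28 forkhead factors, 8 were lower and 2 higher (median 0.07, percentile 47.0, -0.20 to 0.19 over the other settings). Foxs1 was 12.9-fold lower, Foxo4 and Foxf2 were at least 11.0-fold and 9.01-fold lower, and Foxp2 was at least 7.93-fold higher. Of 23 partners and targets of FOXP3, 9 were lower and 2 higher (median -0.19, percentile 13.2). With no filter and no bounds, which lets in members not above background, 12 of 32 were lower and 2 higher (median -0.90, percentile 0.12), and the other settings gave medians from -0.43 to -0.07 within their random lists. Ptpn22 was at least 27.3-fold lower, Lrrc32 (GARP) 7.38-fold and Nt5e (CD73) 5.53-fold lower, and Ikzf4 was 6.54-fold higher. Of 34 NRF2 and antioxidant genes, 12 were lower and 2 higher (median -0.60, percentile 0.71, and -0.39 under quantile normalization and under normexp), with Nqo1, Srxn1 and Txnrd1 9.52-fold, 5.17-fold and 4.77-fold lower and Selenop 8.79-fold higher. Of 19 NADPH oxidases and other producers of reactive oxygen species, 7 were lower and 3 higher (median -0.42, percentile 5.66). The median was -0.61 for the mean over detected probes, at percentile 1.56, and ran from -0.72 to -0.22 within the random lists of the other settings. Ptgs2 (cyclooxygenase-2) was 116-fold lower (-6.85 ± 0.21), Prodh was 5.17-fold lower, and the leukocyte genes Ncf4 and Alox5 were at least 16.3-fold and 6.47-fold lower beside the lower macrophage markers.

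Lists of matrix and mesenchymal genes had medians above the middle 95% of random lists, with members in both directions in most of them. Of 41 extracellular matrix genes, 15 were higher and 8 lower (median 0.59, above each random list). Quantile normalization gave 16 higher and 5 lower (median 0.52), and normexp 16 higher and 4 lower (median 0.47). The matrix median was 0.34 when scaled to the median of all probes, 0.33 with detection on both arrays or with no filter, and 0.26 for the mean over detected probes. The proteoglycans Ogn and Dcn (decorin) were 30.7-fold and 6.70-fold higher, Dpt 11.46-fold and Col3a1 7.501-fold higher. Cartilage and bone markers were 13 higher and 1 lower of 18 (median 1.84, above each random list), or 7 and 1 of the 11 detected on both arrays. Besides Cnmd and Omd, the cartilage collagen Col9a1 and Matn1 (matrilin) were at least 74.0-fold and 61.4-fold higher. Of 10 adipocyte markers, 7 were higher and 0 lower (median 1.53, percentile 99.99). Cebpa, Lpl and Agt were 17.6-fold, 6.16-fold and 6.09-fold higher and Cidea was at least 13.98-fold higher. Of 21 mesenchymal and fibroblast markers, 9 were higher and 2 lower (median 0.53, percentile 99.99, and 0.28 when scaled to the median of all probes), among them Pdgfra and Lum at 5.20-fold and 4.57-fold higher. HOX and imprinted embryonic genes were 12 higher and 3 lower of 25 (median 0.94, percentile 99.99, and 0.55 under normexp). The imprinted genes Mest, Peg3 and Cdkn1c were 41.5-fold, 25.1-fold and 12.4-fold higher, and the posterior gene Hoxa11 was at least 9.39-fold lower.

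Of 39 lysosome and autophagy genes, 5 were higher and 1 lower (median 0.25, percentile 99.86). The lysosome median was 0.57 under quantile normalization, with 8 higher, 0.53 under normexp, and 0.0098 when scaled to the median of all probes, with 2 higher. Ctsf was 5.93-fold and Gaa 2.65-fold higher, Ctso at least 2.36-fold higher, and Ctss, also a macrophage marker, lower. Of 31 glycolysis and hypoxia genes, 12 were lower and 9 higher (median -0.49, percentile 2.71). This list lay just inside the middle 95% of random lists, and under the other settings its percentile ran from 0.18 to 2.48, outside it. The named members were Hk2, Egln3, Ankrd37 and Slc2a1, between 8.26-fold and 3.70-fold lower. Of 50 oxidative phosphorylation genes, 45 were within 2-fold, 4 lower and 1 higher (median -0.35, percentile 26.7, -0.59 to 0.01 over the other settings). When scaled to the median of all probes, 10 were lower and 1 higher. Cycs, Ndufab1 and Uqcrc1 were 3.45-fold, 2.48-fold and 2.37-fold lower, and Ppargc1a was at least 8.56-fold higher. Of 32 unfolded protein and integrated stress response genes, 6 were higher and 1 lower (median -0.01, percentile 89.7, -0.25 to 0.19 over the other settings). Ddit3 (CHOP), Trib3, Atf3 and Vldlr were 7.07-fold, 4.30-fold, 4.12-fold and 3.16-fold higher. Of 29 apoptosis genes, 5 were higher and 6 lower (median 0.08, percentile 65.0, -0.17 to 0.10 over the other settings). Scaling to the median of all probes gave 1 higher and 8 lower. Bmf was at least 17.7-fold higher, Casp1 at least 16.03-fold lower, and Pmaip1 and Tnfrsf10b 11.49-fold and 4.39-fold lower. Under at least 1 other setting the median changed sign for the forkhead, apoptosis, oxidative phosphorylation, stress response, lymphocyte, endothelial and neural lists, each of which lay within the middle 95% of random lists.

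Markers of other cell types gave a mixed picture. Of 22 epithelial markers on the array, 9 had a fold, and 6 of these were lower and 1 higher (median -1.44, percentile 0.7). Normexp gave 3 lower and 0 higher (median -0.94), no filter and no bounds a median of -0.92, and detection on both arrays 3 lower of 5. Perp and Krt19 were 62.3-fold and 37.1-fold lower and Krt18 and Krt7 at least 53.3-fold and 3.63-fold lower. Of 9 skeletal muscle markers, 4 were lower and 2 higher (median -0.53, percentile 7.06, -0.78 to -0.24 over the other settings). Chrna1 was at least 16.9-fold lower, Tnnt2 and Acta1 9.81-fold and 7.87-fold lower and Tnnt1 7.55-fold higher. Of 11 neural and glial markers, 5 were lower and 3 higher (median -0.16, percentile 22.7, -0.74 to 0.03 over the other settings). S100b was 13.9-fold higher, Stmn2 and Nes (nestin) both 13.3-fold lower and Fabp7 at least 7.11-fold lower. Endothelial markers were 3 higher and 3 lower of 11 (median 0.06, percentile 42.5, -0.53 to 0.26 over the other settings), or 2 higher and 0 lower under normexp. Erg and Tek were at least 4.70-fold and 4.18-fold higher, and Esam and Robo4 at least 3.48-fold and 3.06-fold lower. Of 6 lymphocyte markers, 1 was higher, Lck at 4.50-fold, and 0 lower (median 0.05, percentile 33.5, -0.89 to 0.19 over the other settings). Of 2 erythroid genes measured, Tfrc, the transferrin receptor of dividing cells, was 4.53-fold lower. Of 3 sex-linked genes measured, Xist was 2.07-fold higher (1.05 ± 0.20), Eif2s3y 3.08-fold lower (-1.62 ± 0.21), and the third within 2-fold. Of 14 housekeeping genes, 3 were lower, Tfrc, Pgk1 (3.502-fold) and Hprt (2.58-fold), and 0 higher (median -0.22, percentile 64.0, -0.46 to -0.03 over the other settings).

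**Figure D2:**
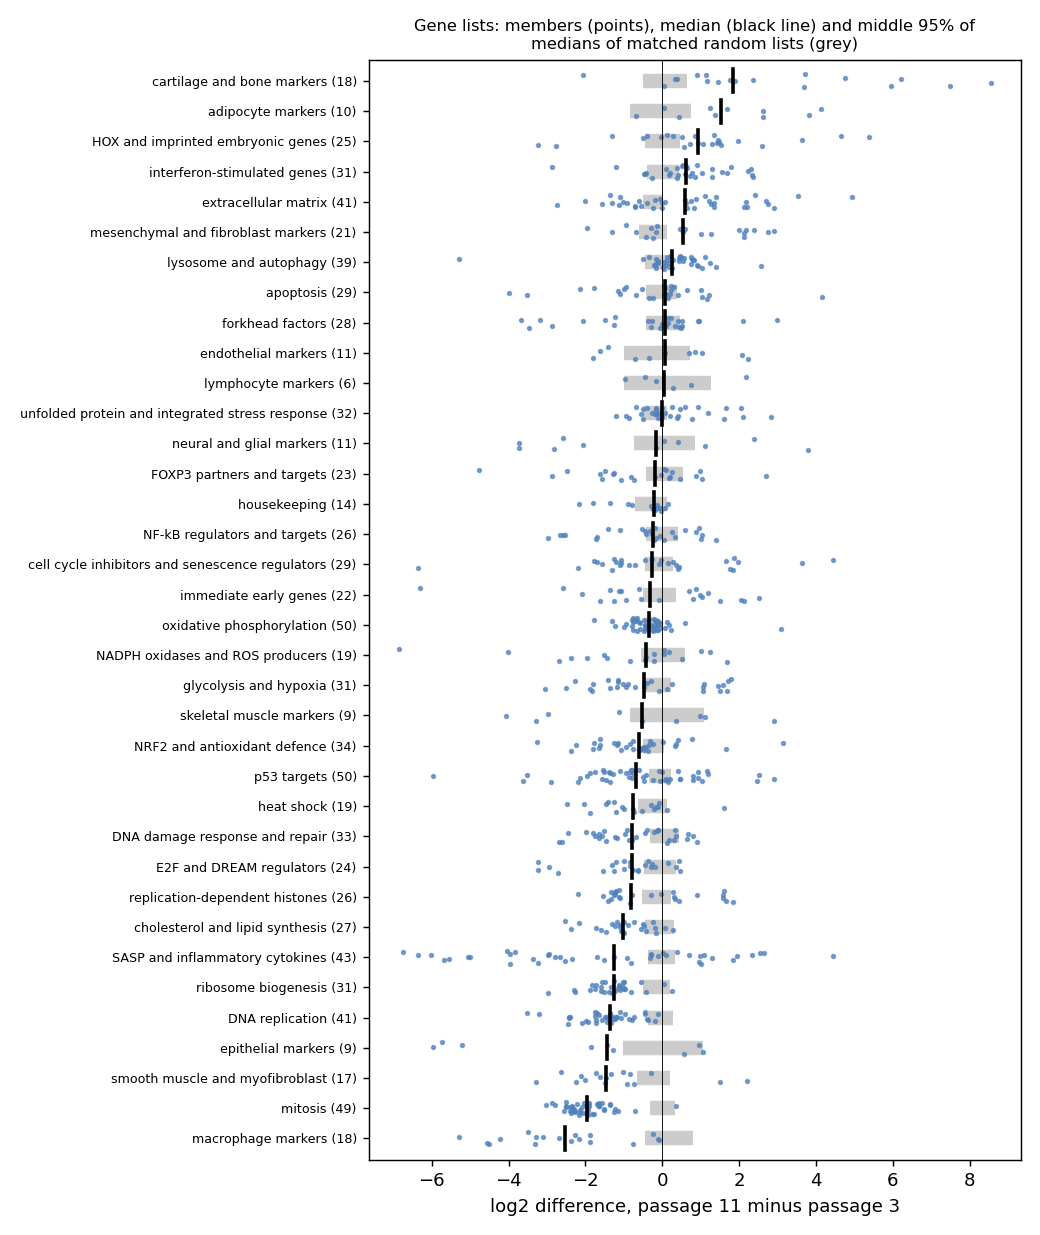
Log2 differences, passage 11 minus passage 3 (x axis), for each list with at least 5 measured members (y axis, number measured in brackets). Blue points are genes, the black line is the list's median and the grey bar the middle 95% of the medians of 10000 matched random lists; the mitosis median (-1.97) lies far left of its bar and the cartilage and bone median (1.84) far right.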

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

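Of the tests in this part, those of scaling, swapped labels, male and female shares and slide were chosen after the result was seen. The lists of further macrophage genes, ERK output genes and quiescence genes, with their limits, were written after the patterns were seen but before their own values were, except for Ccnd1, Lif and Il1rl1 in the ERK list and Rbl2 in the quiescence list. Single genes named here as going against an explanation were chosen after their values were seen.

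Signal appeared in probes that the gene results leave out. Of the 11914 probes with no gene name, 39.1% were well above background at passage 3 and 48.5% at passage 11, against 1.31% and 1.96% of the 153 negative control spots. The share also rose among named probes, from 61.4% to 67.9%, so the rise is not particular to unnamed ones. Of 5491 unnamed probes with a fold, 790 were 2-fold or more higher and 845 lower. Among 14161 named genes with a fold, 2389 were higher and 2439 lower.

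Macrophage markers were lower at passage 11. Scaling cannot account for this, since the median stayed at -1.80 or lower under every scaling tried. Fewer macrophages in the passage 11 culture may account for it. A second list with no gene of the first had a median of -1.39, with 20 of 31 members lower and 2 higher. Against fewer macrophages, the known macrophage markers Itgam, Aif1 and Adgre1 were at -0.11, -0.09 and -0.23. Itgam, however, had scaled signals of 22939.3 at passage 3 and 21236.3 at passage 11, against 1355 at passage 3 for Tyrobp. Whether so bright an Itgam signal came from macrophages was not tested, so its weight here is uncertain. In the second list Pf4 was at 1.74 and Selplg was at least 2.64-fold higher. Its members Lst1, Tlr13, Apbb1ip and Plek were at 0.15, -0.21, -0.32 and -0.42. Ctss of the first list is also on the lysosome list. Lower expression within cells that stayed, and the labelled passage itself, remain open and were not tested.

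Secreted cytokines and proteases, the class that senescent cells are known to release, were more often lower than higher in the array labelled senescent. A swap of the 2 labels is argued against by the mitosis median of -1.97, and scaling by the list's median, which stayed at -0.83 or lower under every scaling tried. Single genes were divided on a swap. Cdkn1a, 2.96-fold lower, would go with it, while Cdkn2a, 3.68-fold higher, and Lmnb1, 4.55-fold lower, would not. Lower output of the ERK pathway at passage 11 is a candidate explanation: 19 of 26 ERK output genes were lower and 1 higher (median -1.81, below each random list). Against it, Etv1 was 5.02-fold higher, Spry1, Spred1, Spred2 and Etv5 were at 0.09, -0.16, -0.36 and -0.33, and the immediate early genes Fos and Ier2 were 5.74-fold and 4.40-fold higher. Slide and scan day, and passage itself, remain open. So does a change in cell types, since macrophage (median -2.53) and epithelial markers (median -1.44) were lower too. It was not separated from ERK output.

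The cartilage and bone, adipocyte, and combined HOX and imprinted lists had medians above the middle 95% of random lists at passage 11. Imprinted genes had no list of their own. The HOX clusters, taken as symbol families after their values were seen, had medians of both signs. Hoxa genes were higher in 4 and lower in 3 of 11 (median 0.72, percentile 90.1), and Hoxb in 3 and 0 of 8 (median 0.85, percentile 98.1). Hoxc genes were higher in 1 and lower in 4 of 8 (median -0.82, percentile 5.35). Of these, only the Hoxb median lay outside the middle 95% of random lists. A shift toward quiescence may go with these 3 higher lists, since 22 of 32 quiescence and serum withdrawal genes were higher and 1 lower (median 1.49, above each random list). Against it, Cited2 was 4.28-fold lower, Nr1d1 and Gas7 were at -0.99 and -0.84, and Klf9, Per1, Irs2 and Ypel5 were at -0.03, -0.05, -0.05 and 0.08. As mitosis genes were lower too, the quiescence list cannot separate quiescence from the labelled senescence. It also does not link quiescence to the cartilage, adipocyte and imprinted genes. Different embryos behind the 2 cultures stay open. Xist minus the mean of 2 Y-linked genes was 2.15 ± 0.25 log2. Xist was at 1.05, Eif2s3y at -1.62 and the other Y-linked gene at -0.57. These opposite directions go with a different share of male and female cells in the 2 cultures. The Y-linked genes lay 1.05 ± 0.29 log2 apart, however, and only within-array error is known. A different share of male and female cells can therefore be neither shown nor excluded. With 2 slides for 2 arrays, slide and scan batch cannot be told apart from passage.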

How the results depend on the processing

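No list outside the middle 95% of random lists changed direction or came inside it under any of the 7 alternatives run on lists, with percentiles per setting added after seeing the data. Glycolysis and hypoxia left it under each of them, FOXP3 partners and targets with no filter and no bounds, and producers of reactive oxygen species for the mean over detected probes. Of 252 such list values, 238 stayed within the half-width of the random lists' middle 95% of the main value and 14 did not. The counts of genes moved by over 1.5 times only with the threshold: at 1.5-fold 3877 were higher and 3868 lower, and at 3-fold 1211 and 1231, as the threshold itself sets. With normexp on median signals, then quantile (added after seeing the data), the medians were -0.83 for the SASP list, 0.53 for lysosome, -0.021 for oxidative phosphorylation, -0.37 for heat shock and -1.80 for macrophage markers. Quantile normalization gave 0.57 for lysosome, 0.0145 for oxidative phosphorylation and -0.38 for heat shock. Scaling to the median of all probes gave -0.59 for oxidative phosphorylation. Detection on both arrays gave -0.86 for the SASP list and 0.33 for extracellular matrix. No filter and no bounds gave -0.90 for FOXP3 partners and targets and 0.33 for extracellular matrix, and the mean over detected probes gave 0.26 for extracellular matrix. Scaling to the median of all probes moved the random lists too: oxidative phosphorylation lay at percentile 27.3, against 26.7 in the main setting. The list members that enter differ with detection on both arrays and with no filter and no bounds. Causes were otherwise not tested. Of 1001 values of named genes, 743 moved by less than the error-model SE, 258 by more and 0 reversed. Of the 4828 genes past 2-fold, 70.8% kept their direction past 2-fold under normexp and at least 78.8% under each other setting at the same threshold. Signal over background limits the dim genes, where bounds replace folds. The normexp alternative on mean signals and all Illumina alternatives were not run. No paired analysis was possible because each group is 1 array.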

Other observations

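The symbol families in this part were chosen after their values were seen, from 227 families of at least 8 genes sharing a symbol stem. Of these, 47 lay outside the middle 95% of random lists, against 11.3 for chance with independent genes. The late cornified envelope (Lce) genes, which build the outer layer of skin, were lower in 11 of 13 members (median -3.87, and -1.84 at its smallest among the other settings), beside the lower epithelial markers. Other families with epithelial members lay within the middle 95% of random lists. Keratin (Krt) genes were lower in 8 of 19 and higher in 2 (median -0.36, percentile 5.36). Claudin (Cldn) genes were lower in 3 of 12 and higher in 1 (median 0.245, percentile 54.4). Beta-tubulin (Tubb) genes were lower in 7 of 8 (median -1.70), and nucleoporin (Nup) genes in 9 of 19 with 0 higher (median -0.92). Chemokine (Ccl) genes were lower in 8 of 13 and higher in 1 (median -1.53, and -0.86 at its smallest among the other settings), beside macrophage markers that were lower in 14 of 18 (median -2.53). Frizzled (Fzd) Wnt receptors were higher in 8 of 10 and lower in 1 (median 1.68). Clustered protocadherin beta (Pcdhb) genes were higher in 10 of 14 and lower in 0 (median 1.77, and 1.15 at its smallest among the other settings). Collagens (Col) were higher in 16 of 36 and lower in 6 (median 0.79, up to 1.35), and zinc finger (Zfp) genes were higher in 77 of 343 and lower in 10 (median 0.46, down to 0.22). Keratin and claudin genes aside, the direction of each of these medians held under every setting run. Lce and Pcdhb members are close copies, and their probes were not checked for sharing signal.

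The difference also went with signal level. Among genes above background on both arrays, the median log2 difference was 0.14 for the 2248 dimmest and -0.34 for the 1184 brightest.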
